A study of Arabidopsis thaliana with 12 samples.

How the data were processed

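The series holds 12 ChIP-seq libraries from Arabidopsis thaliana seedlings: input and anti-Flag IP libraries of Col-0 and of the FL3-Flag line, with 3 replicates of each. Per the labels' protocols, seedlings were grown for 10 days, and 1 g of material was cross-linked with 1.5 mM EGS, a protein cross-linker, for 30 minutes. The series design gives continuous blue light at 30 µmol per square metre per second. The series title names FL1, whereas its design text and every tagged sample name FL3, and the samples are described here by their own labels. The labels do not say whether replicates came from separate plant cultures, so p-values measure the spread between these libraries, which may be technical.

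The deposited files hold raw read counts, 1 file for each of the 6 IP libraries, over the same 2436 merged peaks. The unit was taken from the values, which are whole numbers with different totals per library. Per the submitters' processing notes, BWA 0.7.17-r1188, MACS3 3.0.0a7, deepTools 3.5.1, ChIPseeker 1.34.1 and genome build TAIR10 were used, with no role stated for each. How peaks were called and merged, from which libraries, and how the authors counted reads in them are not given in the sources used here. If the IP libraries themselves were used to call the peaks, the same reads chose the peaks and tested them. Duplicate removal, mapping quality limits and treatment of reads with several matches are likewise not given, and these could set the counts of peaks in repeated sequence. Reads outside the merged peaks are not in these counts, so the depth of the whole libraries is unknown and scaling rests on the peaks themselves. The input counts, peak coordinates and peak lengths were not used here, so counts are per peak and not per base.

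Each library was assigned to its genotype and replicate number from its title. FL3-Flag IP was compared with WT IP in edgeR 4.0.16 (R 4.3.3) with trimmed-mean-of-M-values (TMM) factors, robust dispersion estimates and the quasi-likelihood F test, with genotype as the only term. Peaks were called at a Benjamini-Hochberg adjusted p below 0.05 over all 2436 peaks. The low-count filter of edgeR (minimum count 10) removed 0 peaks, since the weakest peak averaged 88.8 reads. A scaled count is a count divided by its library's TMM-adjusted size and multiplied by the mean of those sizes. Standard errors of log2 changes were computed from the replicates' log2 scaled counts. Totals and shares per library were compared by exact two-sided permutation tests, for which 0.1 is the smallest p. Over the 6 such measures compared, the smallest Benjamini-Hochberg adjusted p of these exact tests was 0.2. Counting error is covered by the replicate spread, and no molecular identifiers are recorded.

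The rule for naming peaks was fixed before the data were examined, as were the alternatives except those said to be added. It took the 12 largest rises and the 12 largest falls among called peaks whose genotypes did not overlap. It also took the 4 peaks with the highest mean. The peaks themselves were picked by this rule from the same counts that gave their changes and p-values. They are therefore selected extremes and not peaks chosen in advance. Planned tests of gene lists (cell cycle regulators, DNA replication, light signalling, light-harvesting, circadian clock, auxin), of genomic features, of separately called peak sets and of binned profiles were not run, since the counts carry no gene names, coordinates or bins. The thresholds that define the abundance groups of 812 peaks and the 17 peaks above 4096 scaled counts were chosen after seeing the data.

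Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, upper-quartile factors, scaling by the total, no scaling, no filter, a stricter filter, an adjusted p of 0.01, the replicate number as a block and leaving out each library. Leaving out the 4 dominant peaks, scaling by the total of the other 2432 peaks, and abundance-dependent scaling (cyclic loess offsets from limma 3.58.1, 3 iterations, on log2 of the count plus 0.5) were added after seeing the data. The edgeR procedure was tested on simulated data for all 2436 peaks of the FL3-Flag against WT comparison. These used each peak's mean scaled over all 6 libraries, the TMM-adjusted library sizes and the estimated dispersions. The procedure recovered 85 of 100 peaks changed 1.5-fold and 100 of 100 changed 2-fold, and it called 5 of 2236 unchanged peaks. The changed peaks were drawn at random, with no common fall of the dominant peaks and no trend with abundance. The simulation therefore could not test the scaling of the libraries.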

Results

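Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to ask whether the Arabidopsis thaliana protein FL3 associates with chromatin in blue light. Seedlings of the wild-type accession Col-0 and of a line carrying FL3 with a Flag epitope tag were grown for 10 days, and chromatin was pulled down with anti-Flag beads. Col-0 carries no tagged FL3, so its pull-down measures what the beads recover without the tag. Read counts over 1 common set of 2436 merged peaks were analysed for 3 Col-0 (WT) immunoprecipitation (IP) libraries and 3 FL3-Flag IP libraries. Counts of the 6 input libraries of the series were not used here. The peaks carry running IDs from Merge_peak_1 to Merge_peak_2436. Their coordinates, lengths and neighbouring genes were not used here, so each peak is named by its ID alone and no gene is assigned to it.

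The reads over the merged peaks were dominated by 4 peaks with neighbouring IDs, Merge_peak_2431 to Merge_peak_2434. These held 84.2% ± 1.54 of the peak reads in the WT IP and 76.7% ± 0.804 in the FL3-Flag IP (SD, n = 3 each). All 3 FL3-Flag libraries lay below all 3 WT libraries in this share. The exact two-sided permutation test gave p = 0.1, which is the smallest p that 3 against 3 libraries allow.

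Total counts were 9155289, 7874284 and 8274961 in WT replicates 1 to 3, and 5716609, 6237558 and 5300645 in FL3-Flag replicates 1 to 3. The mean FL3-Flag total was 0.682 of the mean WT total, again with no overlap between the genotypes (exact permutation p = 0.1, two-sided). The other 2432 peaks held 1327870 ± 30003 reads in the WT IP and 1343217 ± 149804 in the FL3-Flag IP (SD, n = 3 each; exact permutation p = 0.9, two-sided). The genotypes therefore differed in total mainly through the 4 dominant peaks. The median peak held 202 to 256.5 reads per library.

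**Figure D1:**
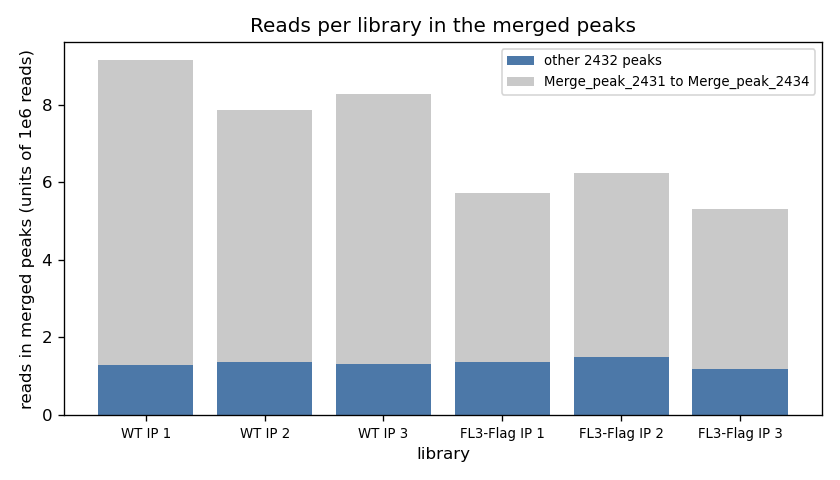
Reads in the merged peaks per library (axis in units of 1e6 reads), split into the 4 dominant peaks (grey) and the other 2432 peaks (blue), each bar being 1 library. The WT bars reach 7874284 to 9155289 reads and the FL3-Flag bars 5300645 to 6237558, while the blue parts overlap between the genotypes.

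The comparison of FL3-Flag IP with WT IP asked which peaks gained or lost reads when the tag was present. Of the 2436 peaks, 432 were higher and 375 were lower in the FL3-Flag IP, and 1629 did not pass the test (edgeR quasi-likelihood test, adjusted p below 0.05). Most of these changes were small. The median log2 fold change was 0.57 among the peaks called higher and -0.45 among those called lower, and 510 of the 807 called peaks changed by less than 1.5-fold. Only 10 peaks rose by 2-fold or more, and 12 fell by 2-fold or more. Without WT replicate 2 these counts were 19 and 16, and without WT replicate 1 they were 12 and 7. In 42.5% of all peaks the scaled counts of the genotypes did not overlap, against 10% by chance for 3 against 3 libraries.

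The split between rises and falls depended on the scaling of the libraries. Scaling by the total over all peaks, which the 4 dominant peaks set, shifted the median log2 change of all peaks from 0.00 to 0.53 and gave 1837 peaks higher and 33 lower. Upper-quartile scaling gave 571 higher and 285 lower. Counts as deposited, with no scaling, gave 234 higher and 230 lower. Scaling by the total over the other 2432 peaks turned the balance, with 388 higher and 444 lower. Rises and falls of 2-fold or more numbered 333 and 0 under the total over all peaks, 20 and 8 under upper-quartile scaling, and 11 and 3 under abundance-dependent scaling. The changes below are therefore relative to the median peak. Without FL3-Flag replicate 2 the peaks called higher fell to 279. The 11 rises under abundance-dependent scaling were not the same peaks as the 10 under TMM scaling. Merge_peak_1559, Merge_peak_1558, Merge_peak_56 and Merge_peak_1501 stayed above 2-fold. Merge_peak_771, Merge_peak_343, Merge_peak_706, Merge_peak_1419, Merge_peak_2066 and Merge_peak_713 fell to log2 changes between 0.57 and 0.77. The rest of the 11 were peaks that came in, among them Merge_peak_2090 and Merge_peak_2095, at log2 changes of 1.00 and 1.11. The other peaks that came in are not listed here.

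3 peaks stood apart from all others by the size of their rise. Merge_peak_1559 rose 9.67-fold, from 125 ± 19.6 scaled counts in the WT IP to 1215 ± 94.2 in the FL3-Flag IP (SD, n = 3 each), a log2 change of 3.27 ± 0.15 (SE; edgeR adjusted p = 2.252e-84). Its neighbour by ID, Merge_peak_1558, rose 8.09-fold, from 194 ± 16.2 to 1572 ± 135 scaled counts (log2 change 3.02 ± 0.10, edgeR adjusted p = 1.257e-82). Merge_peak_56 rose 3.86-fold, from 55.9 ± 12.8 to 216 ± 15.9 scaled counts (log2 change 1.95 ± 0.21, edgeR adjusted p = 1.761e-19). All 3 FL3-Flag libraries exceeded all 3 WT libraries at each of these peaks, as the rule for naming peaks required. The smallest of the 3 log2 changes lay between 1.60 and 2.47 over the alternative settings run.

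The other 9 of the 12 largest rises were close to 2-fold and came from weak peaks. They ran from 2.23-fold at Merge_peak_1501, which went from 118 ± 35.8 to 263 ± 27.9 scaled counts, to 1.94-fold at Merge_peak_1586, which went from 82.8 ± 4.02 to 162 ± 26.0. Merge_peak_771, Merge_peak_343, Merge_peak_706, Merge_peak_1419, Merge_peak_2066, Merge_peak_713 and Merge_peak_2223 lay between them. None of these 9 peaks averaged more than 263 scaled counts in the FL3-Flag IP. With abundance-dependent scaling, Merge_peak_771 and Merge_peak_2066 no longer passed the test (edgeR adjusted p = 0.0642 and 0.0511).

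The 12 largest falls came from stronger peaks. Since Col-0 carries no tagged FL3, a count below the WT IP cannot be read as lost FL3-Flag binding. The neighbouring peaks Merge_peak_230 and Merge_peak_229 were 2.65-fold and 2.59-fold lower in the FL3-Flag IP. The first went from 2405 ± 296 to 907 ± 176 scaled counts and the second from 2484 ± 405 to 958 ± 89.9 (SD, n = 3 each; edgeR adjusted p = 5.258e-24 and 3.622e-31). Merge_peak_775 was 2.59-fold lower and Merge_peak_2069 2.40-fold lower, with log2 changes of -1.37 ± 0.18 and -1.26 ± 0.09 (SE). The list went on with Merge_peak_1508, Merge_peak_1323, Merge_peak_214, Merge_peak_2339, Merge_peak_1906, Merge_peak_1793 and Merge_peak_600, and ended at Merge_peak_1252, which went from 693 ± 78.5 to 348 ± 85.2 scaled counts. In the WT IP these 12 peaks averaged between 693 and 4253 scaled counts. Under the total over all peaks none of the 12 was 2-fold or more lower, although each still passed as lower.

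**Figure D2:**
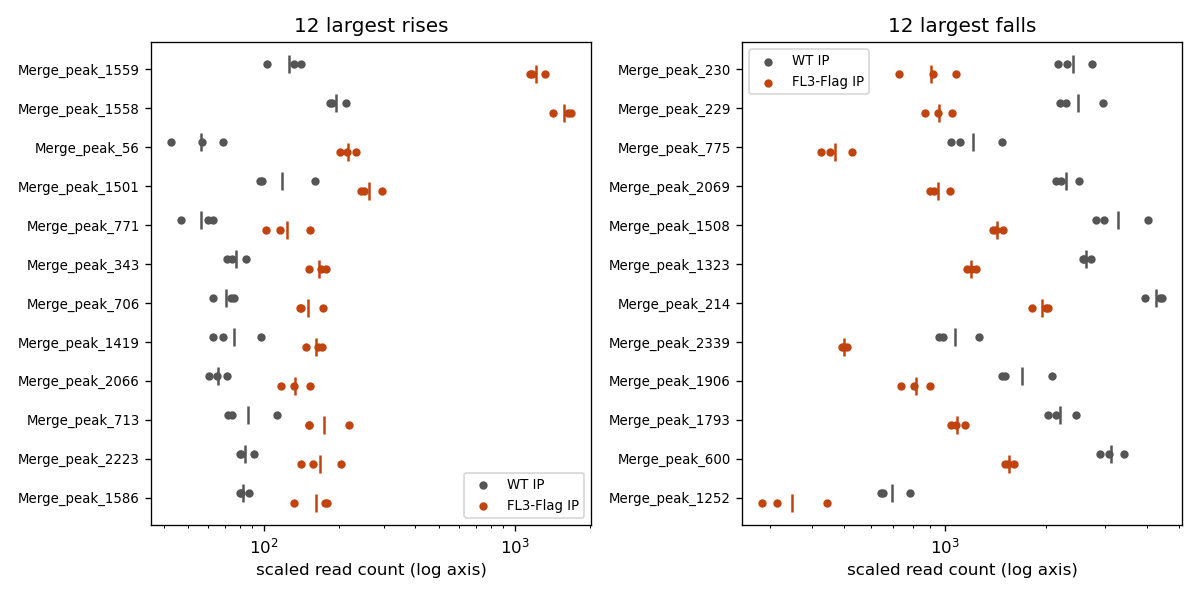
Scaled read counts (log axis) of the 12 peaks with the largest rises and the 12 with the largest falls, each dot being 1 library and each vertical tick the mean of 3 libraries. The genotypes do not overlap at any of the 24 peaks, as the rule for naming them required. Merge_peak_1559 and Merge_peak_1558 are the only ones with a rise above 8-fold.

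The direction of change followed the abundance of the peaks. Among the 812 peaks with the fewest reads (88.7 to 172 mean scaled counts), 240 were higher in the FL3-Flag IP and 14 lower. Among the next 812 peaks, 110 were higher and 53 lower. Among the 812 with the most reads, 82 were higher and 308 lower. The balance of higher and lower calls differed between the weakest and the strongest 812 peaks (Fisher's exact test, two-sided, p = 2.087e-84, over peaks, which are not independent replicates). The median log2 change was 0.17 in the weakest 812 peaks and -0.16 in the strongest 812. With the total over all peaks the balance among the strongest 812 turned to 500 higher and 33 lower calls, against 658 and 0 among the weakest 812. Both medians were then positive, at 0.70 and 0.37, and the difference between them stayed at -0.33. Abundance-dependent scaling, which removes such a trend by construction, brought that difference to 0.01. It gave 67 higher and 69 lower calls among the weakest 812 peaks, and 167 and 150 among the strongest 812. Without FL3-Flag replicate 2 the weakest 812 peaks held 149 higher and 6 lower calls and the strongest 812 held 56 and 246, and without WT replicate 1 the weakest 812 held 200 and 6.

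The spread of counts was correspondingly narrower in the tagged line. The 90th percentile of the peak counts was 8.67 ± 0.375 times the 10th percentile in the WT libraries and 6.19 ± 0.127 times in the FL3-Flag libraries (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest possible).

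**Figure D3:**
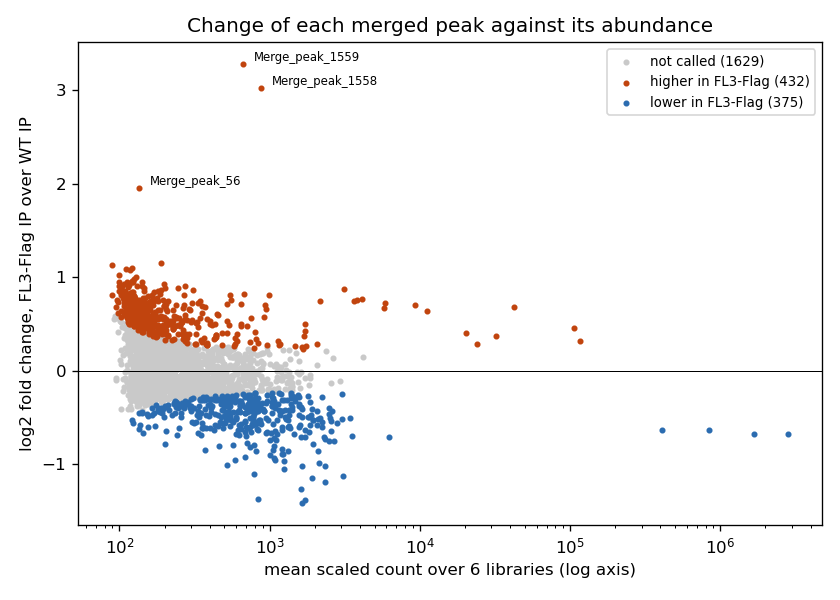
Log2 fold change of FL3-Flag IP over WT IP against the mean scaled count of the 6 libraries (log axis), each dot being 1 of the 2436 peaks, coloured by the edgeR call. Higher calls (432) gather among weak peaks and lower calls (375) among stronger ones, except for a group of very abundant peaks that rose.

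The 4 dominant peaks fell with the other abundant peaks, whereas most of the next most abundant ones rose. The dominant peaks moved together, with log2 changes of -0.67 ± 0.11 at Merge_peak_2433, -0.68 ± 0.11 at Merge_peak_2432, -0.63 ± 0.11 at Merge_peak_2434 and -0.63 ± 0.10 at Merge_peak_2431 (SE; highest edgeR adjusted p = 4.425e-10). Under the total over all peaks, which these peaks largely set, their log2 changes shrank to between -0.14 and -0.10. A further 13 peaks averaged above 4096 scaled counts. Of these, 11 were higher in the FL3-Flag IP, Merge_peak_620 was lower, and Merge_peak_416 did not pass the test. The median log2 change of the 13 was 0.46. They included the runs of neighbouring IDs from Merge_peak_1279 to Merge_peak_1282 and the pairs Merge_peak_647 with Merge_peak_648 and Merge_peak_1515 with Merge_peak_1516, a grouping noticed after the values were seen. Merge_peak_1279 had a log2 change of 0.68 ± 0.08 and Merge_peak_1515 one of 0.70 ± 0.07 (SE; edgeR adjusted p = 6.512e-15 and 2.940e-15). Between 10 and 12 of the 13 were called higher under the alternatives run.

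Replicates of 1 genotype were more alike than libraries of different genotypes. The correlation of log2 scaled counts across peaks was 0.979 to 0.985 within WT, 0.982 to 0.983 within FL3-Flag, and 0.936 to 0.966 between the genotypes. As a check for a library deposited more than once, the chi-square statistic per degree of freedom over the other 2432 peaks was at least 2.90 for every pair of replicates, against read counting error only, so each library was counted as 1 sample. WT replicate 1 was the least like its group, at 6.38 and 6.52 against WT replicates 2 and 3.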

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

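The 28 named peaks kept their direction under every alternative that included them. Leaving aside both filters, which removed 0 peaks and so tested nothing, the call also held in 442 of 444 such values, and the exceptions were Merge_peak_771 (log2 change 0.60) and Merge_peak_2066 (0.57) under abundance-dependent scaling, an alternative added after seeing the data. The counts of called peaks moved by more than 1.5 times under 2 scalings. The total over all peaks gave 1870 calls, 1837 higher and 33 lower, because the 4 dominant peaks, which fell, set that total. No scaling gave 464 calls, 234 higher and 230 lower, all of them among the 807, and the cause was not tested. DESeq2 gave 716 calls, of which 711 were among the 807. Abundance-dependent scaling gave 595 calls, of which 449 were among the 807. Leaving out 1 library at a time gave 558 to 787 calls, 279 to 422 higher and 279 to 368 lower, with the fewest higher calls without FL3-Flag replicate 2. Counts of peaks changed 2-fold or more ranged from 8 to 19 higher and 7 to 16 lower over these runs. The most in both directions came without WT replicate 2. Upper-quartile scaling gave 20 and 8, the total over all peaks 333 and 0, and abundance-dependent scaling 11 and 3. The 11 were in part other peaks than under TMM scaling. The ratio of FL3-Flag to WT totals was 0.682, between 0.653 and 0.712 with 1 library left out, and 0.909 without the 25 most abundant peaks, which include the dominant peaks. The replicate block gave 785 calls, 422 higher and 363 lower. Deviations of same-numbered libraries from their genotype means correlated at -0.01, 0.00 and -0.07 across peaks, so no shared effect of the replicate number was visible. This cannot show whether same-numbered libraries were prepared together. Settings listed beforehand for organelle peaks, separate peak lists, genomic features and gene lists were not run, since the counts carry no such information. Other pseudocounts were listed only for values that are not counts and were not run. The median peak held 202 to 256.5 reads per library. The 85 of 100 simulated 1.5-fold changes that were recovered lay in peaks drawn at random over all abundances. That share is therefore not the recovery at the median depth, and recovery among the weak peaks was not examined separately. Changes below 1.5-fold are the ones most open to being missed.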

Other observations

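All tests in this part except the count of other splits were chosen after the results were seen. Neighbouring peak IDs changed together. If the IDs number the peaks along the genome, which the sources used here do not state, peaks close to each other would share their change. The rank correlation of log2 change between each ID and the next was 0.15 across peaks, against -0.04 to 0.04 for the central 95% of 10000 random orders (permutation p = 0.0001, the smallest these orders give; 0.000167 after adjustment over 5 such tests). Pairs of neighbouring IDs that were both called higher numbered 120, against 76.5 on average in random orders, and pairs both called lower numbered 81 against 57.5 (permutation p = 0.0001 and 0.0002; adjusted 0.000167 and 0.00025). The longest run was the 10 peaks from Merge_peak_2090 to Merge_peak_2099, all called higher. Random order of the IDs is argued against by these counts. Abundance is argued against as well, since the mean count of neighbouring IDs correlated at 0.02 (permutation p = 0.164) and the correlation of changes was 0.17 after abundance-dependent scaling. Regional association of the tagged protein, regional differences in background and broad regions split into several peaks may each give this pattern and stay open without coordinates.

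Relative to the median peak, abundant peaks tended to be lower and weak peaks higher in the FL3-Flag libraries. Under the total over all peaks the medians of the weakest and strongest 812 peaks were both positive, at 0.70 and 0.37. The difference between them was still -0.33. Reads taken up by the 4 dominant peaks would act on all other peaks as 1 factor per library and so leave weak and strong peaks alike. This is argued against as the whole cause, since the median log2 change of the strongest 812 peaks minus that of the weakest 812 was -0.33, and between -0.36 and -0.31 with each library left out. A candidate explanation is lower enrichment over background in the FL3-Flag libraries, which would pull strong peaks down and weak ones up without any binding of FL3-Flag. Enrichment here means what the beads recover at strong peaks, with or without the tag. Col-0 carries no tagged FL3, so a fall below the WT IP cannot be a loss of FL3-Flag binding. The median log2 change of the 227 peaks in the top 10% by mean count, outside the 17 most abundant, was -0.31. This value restates the trend to be explained and so lends the explanation no support. Its prediction, written after the values were seen, also required that none of the 17 most abundant peaks be called higher. That part failed, since 11 of the 17 were called higher. Without peak lengths, abundant but background-dominated peaks cannot be told apart from enriched ones. Lower enrichment therefore stays open for the other peaks, as does an untested effect of the tagged protein itself.

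Merge_peak_56, Merge_peak_1558 and Merge_peak_1559 rose far more than the rest. The trend with abundance, and lower enrichment over background acting through it, are argued against as the whole cause. Abundance-dependent scaling moved the median log2 change of the weakest 812 peaks from 0.17 to -0.03, yet left 3.34 at Merge_peak_1559, 3.15 at Merge_peak_1558 and 1.60 at Merge_peak_56. Extra copies of the DNA under these peaks in the FL3-Flag line, such as sequence carried by the tag construct, may raise IP counts without any binding. The log2 changes of the neighbours Merge_peak_1559 and Merge_peak_1558 differed by 0.26, which does not decide it, and input counts, which would, were not used here. Binding of FL3-Flag at these peaks is the biological alternative that the design names and stays untested against extra copies.

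The real split of the 6 libraries gave 807 calls and the highest of the other 9 splits gave 0, so 1 of 10 splits reached the real count. Each of the other 9 splits mixes the genotypes in both groups, so a genotype difference widens the spread within groups and lowers the calls. Their 0 therefore does not measure how many calls chance would give. With 10 splits the share cannot go under 0.05.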
